A study of Homo sapiens with 6 samples.

How the data were processed

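Total RNA of U87 cells was sequenced in 6 libraries, 3 labelled control and 3 labelled siRBM47 here. Groups and replicate numbers were taken from the sample titles, which read control or siRNA with a number and do not name RBM47. Per the labels' protocols the libraries were made with a kit that does not mark the strand of the RNA. Reads were aligned with HISAT2 2.0.5 and counted with featureCounts 1.5.0-p3 on hg38, per the submitters' processing notes. The annotation release, the strand setting and any filters of the reads are not given in the sources used here. The deposited files hold whole-number counts per gene and FPKM values side by side, per the file headers. The FPKM were used to check the counts and to take a gene length from the ratio of the 2 values, and for no test. The library size that the FPKM imply differed from the total count by factors of 0.956 to 1.055. Rounded totals were 15580000, 17640000 and 18130000 counts in control replicates 1 to 3 and 17600000, 17880000 and 17580000 in siRBM47 replicates 1 to 3. A count of 0 allows up to 3 counts, and intervals and such limits cover counting error only.

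Gene symbols came from a table of gene identifiers, which gave no symbol for 5909 identifiers, 385 of them among the tested genes. Positions, exons and overlaps are from GENCODE release 29 on GRCh38, which does not contain 5567 of the identifiers, and 7 of the listed genes were not found by symbol. Libraries of a group were compared by a chi-square test of counts over genes with at least 20 counts in the pair. The statistic per degree of freedom was 10.74 for control replicates 1 and 2, 144.83 and 117.05 for control replicate 3 against these, and 15.11 to 37.11 among siRBM47 libraries, so no library was counted as a repeat of another.

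Genes were kept by filterByExpr with a minimum count of 10, which left 14578 genes. They were tested with edgeR 4.0.16 (quasi-likelihood fit and test, TMM factors, no block) under R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are siRBM47 over control on the log2 scale, the standard error was taken as the absolute log2 fold change over the square root of F, and CPM values (counts scaled to a common library size) use the TMM-scaled library sizes. Before the data were examined, 33 gene lists were fixed and then tested with camera (limma 3.58.1, preset correlation of 0.01) on log2 CPM with a prior count of 2, adjusted over the lists, with fry and camera with an estimated correlation beside it. The lists are named in the results, where each has its adjusted p.

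The rule for the genes named was also set before the data were examined. It took RBM47 and its related proteins, then the 10 largest increases and 10 largest decreases among genes past the threshold with a mean log2 CPM of at least 3, a proper symbol and groups that do not overlap. It added 5 genes per direction with the smallest p, read as the next 5 not already taken, and up to 4 members of a list with the smallest p, or 2 where no member passed. Only 6 higher genes met the conditions. Some list members that the rule takes are not reported here.

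The alternatives were other scaling factors (RLE, upper quartile), DESeq2 1.42.0, limma-voom, no filter beyond removing genes without counts, a minimum count of 50, a replicate block and each library left out in turn. Library quality weights in limma-voom and an offset for gene length and GC content were added after seeing the data. The edgeR and camera steps were tested on simulated data with the means, dispersions and library sizes of the 14578 genes of this comparison and 200 changed genes. The edgeR step recovered 18% of the genes changed 2-fold and 82% of those changed 4-fold, and 5 of its 106 calls were unchanged genes. A list shifted by 0.7 on the log2 scale was called by camera, and 0 of the other lists were. Neither correlation between genes nor a library that stands apart was among the properties taken from the real data. In the lists past the camera threshold the estimated correlation ran from 0.036 (replication-dependent histones) to 0.6 (cholesterol synthesis). The simulated list result therefore cannot decide whether camera's preset correlation suits the real lists.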

Results

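RNA sequencing was carried out on U87, an established human glioma cell line, in 6 libraries of total RNA. Of these, 3 libraries were labelled control and 3 were labelled siRBM47, for cells given 100 pmol of a small interfering RNA against RBM47, an RNA-binding protein with roles in splicing, stability and editing of transcripts. The comparison addressed which transcripts differ when RBM47 is depleted in these cells. The treatment label of the control cells reads no and does not say whether they were transfected, so an effect of transfection could not be separated from one of the siRNA. Total counts per library ranged from 15580000 to 18130000, rounded, and 14578 genes were abundant enough to be tested. The labels do not say that the replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

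A lower level of RBM47 was not detected in the libraries labelled siRBM47. The gene (ENSG00000163694, GRCh38 chromosome 4, 40423267 to 40630875, minus strand, protein-coding) was measured at 3.03 ± 2.35 CPM (counts scaled to a common library size) in control and 2.84 ± 0.66 in siRBM47 (SD, n = 3 each). In the control libraries the level was 1.62, 1.73 and 5.75 CPM for replicates 1, 2 and 3, from 24, 30 and 108 counts. In the siRBM47 libraries it was 3.54, 2.74 and 2.23, from 64, 48 and 40 counts. RBM47 was thus of low abundance in these cells, at a mean log2 CPM of 1.62, under the 3 asked of genes named by size of change. The exact Poisson 95% interval of control replicate 3 (4.72 to 6.94) lay above that of every other library, and intervals cover counting error only. The log2 fold change was -0.11 (SE 0.50, 95% interval -1.23 to 1.02, adjusted p = 0.942 by the edgeR quasi-likelihood test), which reaches down to a ratio of 0.43. Without control replicate 3 the sign turned to 0.76 (SE 0.36, 95% interval -0.02 to 1.54, adjusted p = 0.152, edgeR), which reaches down to a ratio of 0.98. Because no fall of the targeted gene was detected to check the labels by, directions are given between the libraries labelled siRBM47 and those labelled control.

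Of the proteins related to RBM47, 5 of 9 listed genes were tested, and 0 passed the threshold by edgeR, DESeq2 or limma-voom, with 1 at an unadjusted p under 0.05. SYNCRIP, a relative of RBM47 that binds RNA, was measured at 169 ± 24.0 CPM in control and 234 ± 47.3 in siRBM47 (SD, n = 3), a log2 difference of 0.47 (SE 0.21, adjusted p = 0.305, edgeR). The log2 differences were -0.38 (SE 0.23) for the cytidine deaminase APOBEC3B, -0.16 (SE 0.20) for ADARB1, 0.08 (SE 0.19) for HNRNPR and -0.05 (SE 0.27) for the adenosine deaminase ADAR. Part of the exon sequence of APOBEC3B is shared in position with APOBEC3A on the same strand (18.4%), so its counts are uncertain. The list did not pass (camera adjusted p = 0.99), with 2 members positive and 3 negative. Its median of -0.05 and mean of -0.01 were negative while camera gave the direction as up. Without control replicate 3 the median was 0.22, and APOBEC3B was lower at -0.57 (SE 0.17, adjusted p = 0.0276, edgeR).

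**Figure D1:**
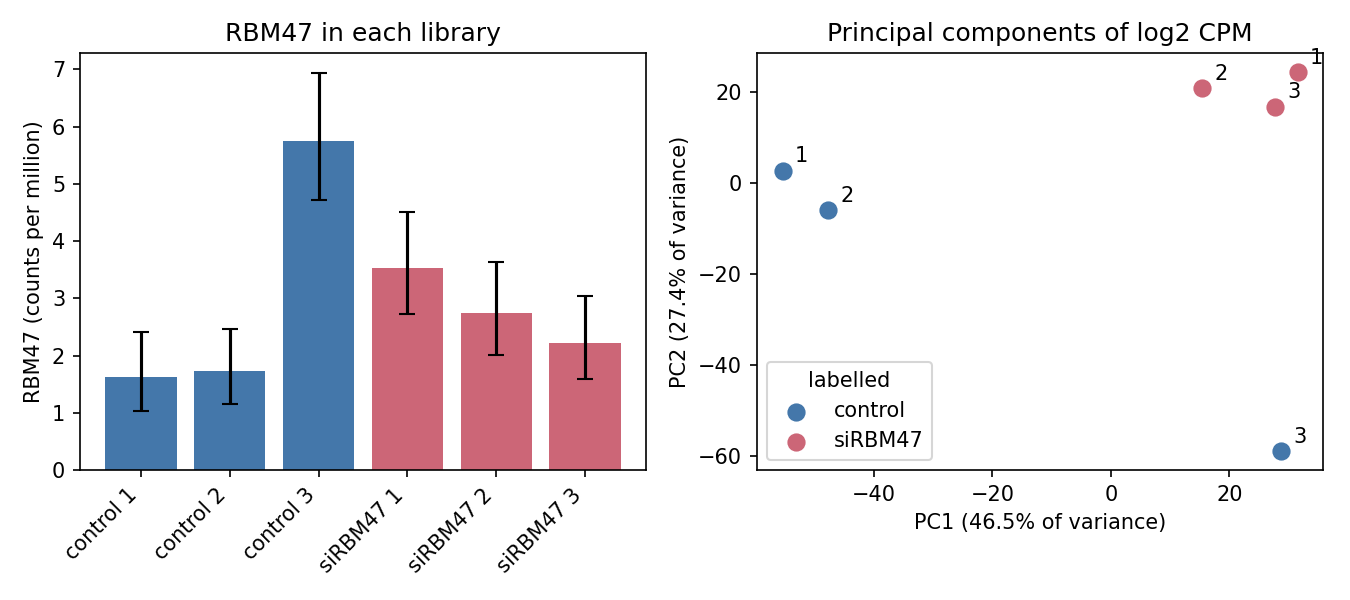
Left, RBM47 in CPM in each library, with bars for the value and whiskers for the exact Poisson 95% interval. Right, the first and second principal components of log2 CPM over the tested genes, with a point per library numbered by replicate; control replicate 3 sits at 28.7 on the first component, among the siRBM47 libraries, and at -58.9 on the second, away from all others.

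In the libraries labelled siRBM47, lists of inflammatory and stress-response genes were lower by camera, as were the single clock genes NR1D1, PER1 and DBP by edgeR, and lists of cytoskeleton and histone genes and the single metallothionein genes MT1E and MT1F were higher. The list calls rest on camera with its preset correlation. None of the 9 was kept with an estimated correlation (adjusted p = 0.708 to 0.721 with an estimated correlation) or by fry (adjusted p = 0.0729 to 0.548 by fry). Camera with an estimated correlation also limits its degrees of freedom to those that the 6 libraries leave. It gave the histone list an adjusted p of 0.708 at an estimated correlation of 0.036. A call lost in that setting, here and below, therefore cannot be put down to correlation between genes alone. MMP1, a collagenase, fell most among the named genes, from 17.2 ± 8.46 to 0.677 ± 0.364 CPM (SD, n = 3; log2 fold change -4.66, SE 0.52, adjusted p = 0.00955, edgeR). MT1E, a metal-binding metallothionein, rose from 122 ± 22.0 to 681 ± 74.6 CPM (log2 fold change 2.48, SE 0.21, adjusted p = 0.00567, edgeR). NR1D1, a repressor of the circadian clock, fell from 70.3 ± 2.36 to 18.2 ± 0.785 CPM (log2 fold change -1.95, SE 0.17, adjusted p = 0.00567, edgeR). By edgeR at an adjusted p under 0.05, 12 genes were higher and 20 lower in siRBM47, and all 32 differed at least 2-fold. Every library of one group lay above every library of the other for all 32 of these genes and for 22.6% of all tested genes. Without ties this share averages 10% over the 10 ways to split the 6 libraries into 3 and 3. Genes share the libraries and the 32 were called on the same values, so neither share is a test.

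Among the higher genes, FABP3, a fatty acid carrier, rose from 2.82 ± 0.704 to 15.7 ± 1.71 CPM (SD, n = 3). MT1F rose with a log2 fold change of 1.92 (SE 0.28). The metallothionein genes are near-identical neighbours on chromosome 16, and counts of MT1E (56625475 to 56627112) and MT1F (56657694 to 56660698) are uncertain where reads fit more than 1 copy. TAGLN, an actin-binding protein of contractile cells, rose from 35.1 ± 9.98 to 109 ± 14.5 CPM. The core histone gene H2BC12 rose by a log2 fold change of 1.54 (SE 0.19), with the same reservation on multigene families. PMEPA1, a target and inhibitor of TGF-beta signalling, rose from 45.2 ± 6.43 to 117 ± 6.32 CPM. The adjusted p of these 5 genes lay between 0.00955 and 0.0372 (edgeR).

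Among the lower genes were other clock transcripts. PER1 fell from 63.8 ± 13.5 to 11.7 ± 2.67 CPM and DBP, a clock-driven transcription factor, from 22.5 ± 2.06 to 5.27 ± 1.62 (SD, n = 3). The exons of NR1D1 and THRA, and those of DBP and SPHK2, overlap on opposite strands by 9.5% and 10.1% of their length, and the kit named in the labels does not mark strand. The same holds for other genes given here, with opposite-strand overlaps of 26.5% for IER3, 21.4% for TPM1, 12.9% for APOBEC3B, 11.4% for TAGLN, 9.2% for ACAT2, 7.6% for MMP1 and 6.0% for NPC1. Cytokine-related transcripts that fell were IL1RN, the interleukin-1 receptor antagonist, with a log2 fold change of -2.54 (SE 0.40), IL24 with -1.96 (SE 0.27), the chemokine CXCL2 with -2.26 (SE 0.34) and the tumour necrosis factor receptor TNFRSF1B with -1.69 (SE 0.21). PREX1, a Rac exchange factor, fell by 2.02 on the log2 scale (SE 0.21). DDIT3, a transcription factor of the stress response, fell from 116 ± 22.3 to 33.3 ± 2.22 CPM, and 31.6% of its exon length is overlapped on the opposite strand by MARS1 and MBD6. Named by p were ICAM5 at -1.49 (SE 0.21), the NF-kB cofactor BCL3 at -1.24 (SE 0.18), the kinase PIM3 at -1.51 (SE 0.23), the endoplasmic reticulum chaperone HSPA5 at -1.21 (SE 0.18) and CEBPB at -1.28 (SE 0.19). HSPA5 was the most abundant of them, at 3030 ± 217 CPM in control and 1310 ± 157 in siRBM47. The adjusted p of these lower genes lay between 0.00955 and 0.0458 (edgeR).

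**Figure D2:**
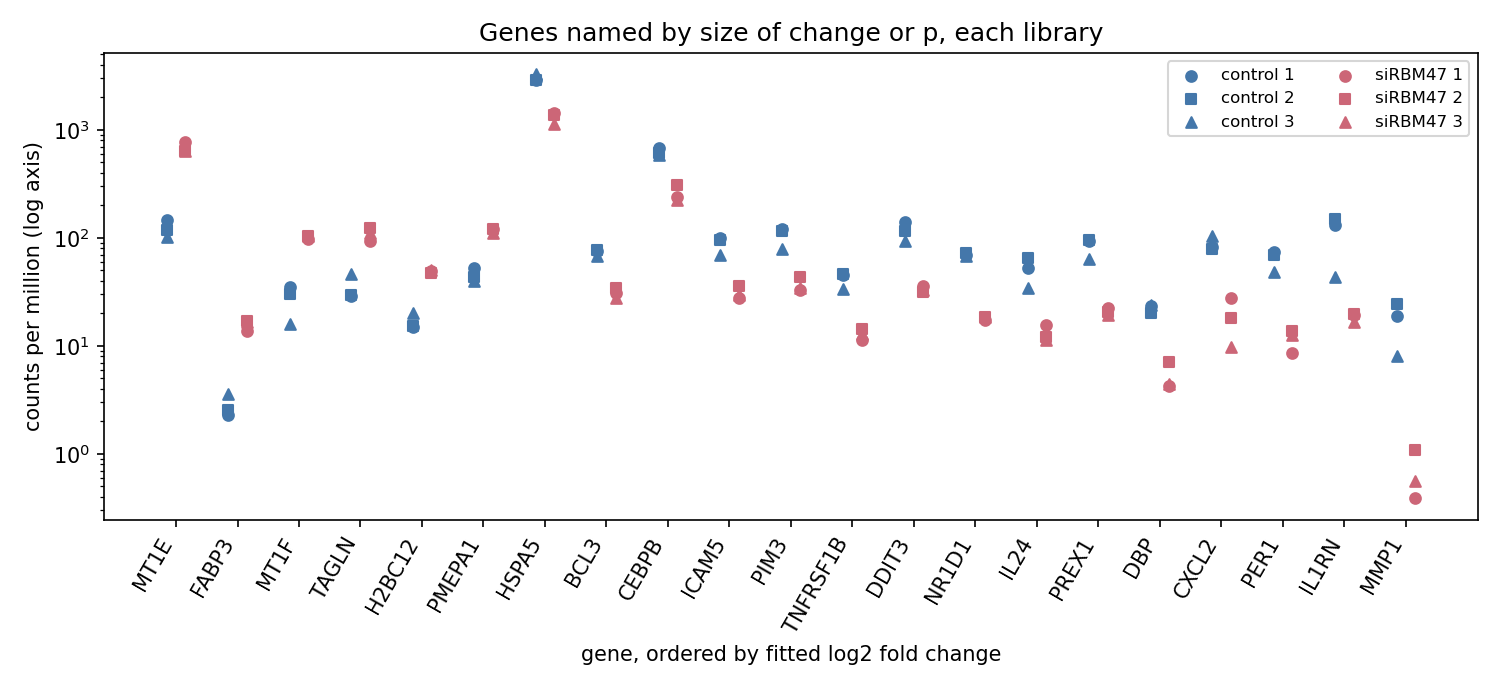
CPM (log axis) of the genes named by size of change or by p, in each library, with colour for the group label and marker shape for the replicate. The rule for naming these genes required groups that do not overlap. For every gene the 3 siRBM47 libraries therefore lie on one side of the 3 control libraries. MT1E was at 634 to 767 CPM in siRBM47 and 101 to 145 in control.

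The number of genes past the threshold rested on single libraries. By edgeR it was 19 without control replicate 1, 12 without control replicate 2 and 3117 without control replicate 3 (1473 higher and 1644 lower), and all 32 genes were among those 3117. Without siRBM47 replicate 1, 2 or 3 it was 0, with 1789, 1816 and 1445 genes at an unadjusted p under 0.05; DESeq2 then gave 374, 283 and 154 genes and limma-voom 0 in each case. With all 6 libraries DESeq2 gave 644 genes and limma-voom 34. The fit without control replicate 3 keeps control replicates 1 and 2, the most alike pair within a group. Their chi-square statistic per degree of freedom was 10.74, against 15.11 to 144.83 for the other pairs. Calls and intervals without control replicate 3, throughout the text, rest on that small spread between controls. The 32 genes were called on the same counts, so their return among the 3117 is not separate support.

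Control replicate 3 stood apart from the other two control libraries. Its Pearson correlation of log2 CPM, across genes, was 0.941 and 0.95 with control replicates 1 and 2, against 0.988 between these, and 0.956 to 0.962 with the siRBM47 libraries. Control replicates 1 and 2 correlated with the siRBM47 libraries at 0.949 to 0.965, a range that contains the values of control replicate 3. Genes are not independent replicates in such a correlation.

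Genes of the NF-kB and inflammatory list were lower as a list in the libraries labelled siRBM47, with 18 of 20 members at a negative log2 difference and a median of -0.99 (camera adjusted p = 1.65e-07). CXCL2 passed the threshold over all genes, and 11 members were lower adjusted over the list alone. IER3 was at 856 ± 69.1 CPM in control and 426 ± 52.3 in siRBM47, CXCL3 at 16.9 ± 1.47 and 6.63 ± 1.98, and the cytokine IL1A at 14.0 ± 1.09 and 4.19 ± 2.21 (SD, n = 3). The difference of control replicate 3 from the mean of control replicates 1 and 2, taken per gene in log2 CPM, had a median of 0.04 over this list. The call was lost with an estimated correlation (adjusted p = 0.708 with an estimated correlation).

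Genes of the unfolded protein response, which serve protein folding in the endoplasmic reticulum, were lower in siRBM47 as a list, with 18 of 18 members at a negative log2 difference and a median of -0.61 (camera adjusted p = 2.97e-06). HSPA5 passed over all genes and 8 members were lower adjusted over the list alone. PDIA4 was at 893 ± 267 CPM in control and 350 ± 46.5 in siRBM47, MANF at 196 ± 29.9 and 99.3 ± 11.4, and HERPUD1 at 228 ± 46.6 and 117 ± 3.42 (SD, n = 3). The integrated stress response and amino acid synthesis list was lower, with 13 members at a negative and 7 at a positive log2 difference and a median of -0.22 (camera adjusted p = 0.0261). DDIT3 and CEBPB passed over all genes and 5 of 20 members were lower adjusted over the list alone. Its member DDIT4 was at 586 ± 87.3 and 216 ± 57.5 CPM, with 41.2% of its exon length overlapped on the opposite strand, and SESN2 at 119 ± 14.9 and 65.0 ± 11.5. With an estimated correlation both calls were lost (adjusted p = 0.708 with an estimated correlation for each). The median of the per-gene difference of control replicate 3 from the other two controls was 0.48 and 0.10 (log2) in these lists, and without this library the integrated stress response list did not pass (camera adjusted p = 0.18).

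Immediate early genes, lysosome and autophagy genes and mitosis and G2/M genes were lower as lists, with medians of -0.43, -0.26 and -0.27 and camera adjusted p of 0.0261, 0.0261 and 0.0154. None of their members passed over all genes by edgeR (0 of 20 in each list), where 6, 4 and 4 members were lower and 2, 0 and 0 higher at an unadjusted p under 0.05, and DESeq2 gave 5, 2 and 1 members and limma-voom 0. Adjusted over the list alone, 4, 2 and 0 members were lower, and 1 immediate early gene was higher. The immediate early genes ZFP36 and KLF2 were at 38.2 ± 6.82 and 41.1 ± 11.9 CPM in control and 14.4 ± 4.53 and 17.3 ± 4.23 in siRBM47 (SD, n = 3). The higher members, named after their values were seen, were FOS at 41.1 ± 31.2 and 121 ± 23.5 CPM (log2 difference 1.56, SE 0.45, adjusted p = 0.146, edgeR) and FOSB at 2.04 ± 1.11 and 5.35 ± 2.95 (1.37, SE 0.49, adjusted p = 0.222, edgeR). Without control replicate 3 both were called higher, at 2.39 and 1.91 (edgeR adjusted p = 1.03e-05 and 0.00919). In that fit 4 immediate early genes were called higher and 6 lower. The cholesterol transporter NPC1 and the protease CTSL were at 250 ± 26 and 166 ± 24.1 against 132 ± 21.9 and 98.2 ± 8.66. The mitotic genes AURKB and CDC20 were at 99.5 ± 49.2 and 231 ± 71.5 against 44.1 ± 8.98 and 138 ± 11.3. The median of the per-gene difference of control replicate 3 from the other two controls was 0.33, 0.35 and -0.48 (log2) in the immediate early, lysosome and mitosis lists. Without control replicate 3 the immediate early and lysosome lists did not pass (medians -0.24 and -0.06, camera adjusted p = 0.468 and 0.317), and all 3 calls were lost with an estimated correlation (adjusted p = 0.708, 0.708 and 0.721 with an estimated correlation, in the order above).

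Lists that were higher in siRBM47 were the replication-dependent histones, cytoskeleton and focal adhesion genes and cholesterol synthesis genes, with medians of 0.60, 0.23 and 0.21 (camera adjusted p = 0.0261 for each). H2BC12 passed over all genes among 10 tested histones and TAGLN among 20 cytoskeleton genes, and 3 and 4 members were higher adjusted over the list alone. Of 20 cholesterol synthesis genes, 0 passed over all genes by edgeR, 2 had an unadjusted p under 0.05, DESeq2 gave 1 and limma-voom 0, and 1 was higher adjusted over the list alone. The histone H2BC5 was at 4.57 ± 2.14 CPM in control and 12 ± 1 in siRBM47 and H4C8 at 0.554 ± 0.258 and 2.09 ± 0.184 (SD, n = 3). TPM1, a tropomyosin, was at 183 ± 99.8 and 547 ± 38.7, CAV1 at 1240 ± 392 and 2410 ± 260, and ACTB at 6680 ± 316 and 10100 ± 758. The sterol enzyme ACAT2 was at 27.7 ± 6.19 CPM in control and 52.5 ± 5.06 in siRBM47. In these 3 lists the per-gene difference of control replicate 3 from the other two controls had medians of 0.58, 0.47 and 0.97 (log2). The medians of the log2 differences without control replicate 3 were 1.13, 0.38 and 0.71 (camera adjusted p = 0.00954, 0.00445 and 3.11e-05). With an estimated correlation the calls were lost (adjusted p = 0.708, 0.721 and 0.721 with an estimated correlation).

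**Figure D3:**
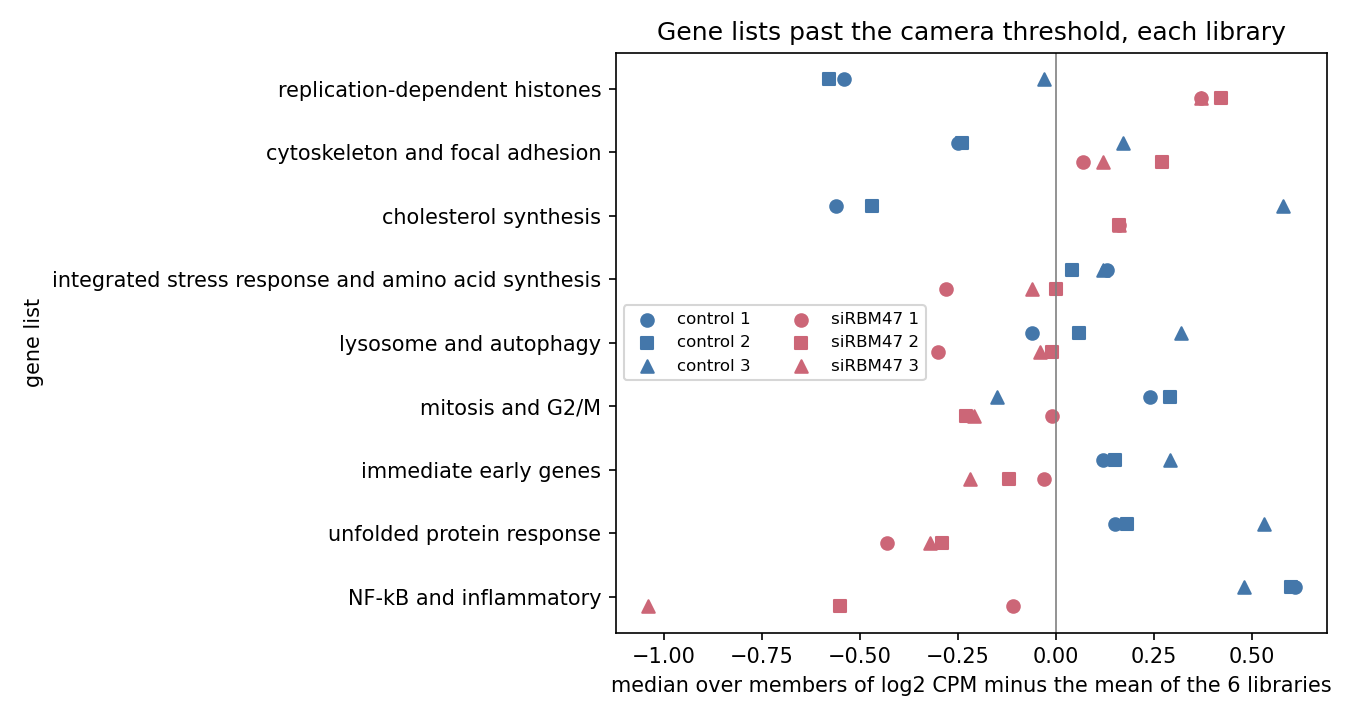
For the 9 lists past the camera threshold, the median over members of log2 CPM minus the mean of the 6 libraries, with a point per library, colour for the group label and marker shape for the replicate. For the NF-kB and inflammatory and the unfolded protein response lists all control libraries lie above all siRBM47 libraries, while for cholesterol synthesis control replicate 3 lies above the siRBM47 libraries and the other two controls below.

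The other 24 of the 33 lists did not pass by camera. PMEPA1 passed over all genes in the TGF-beta list (camera adjusted p = 0.313, median 0.12), where TGFBR2 was at 95.9 ± 46.6 CPM in control and 225 ± 6.50 in siRBM47 (SD, n = 3). Adjusted p by camera was 0.122 for extracellular matrix, 0.156 for cytosolic ribosomal proteins, 0.168 for mesenchymal, for NRF2 targets and for splicing factors, 0.19 for p53 targets and 0.202 for the interferon response. It was 0.213 for Wnt, for oxidative phosphorylation and for mitochondrially encoded genes. For hypoxia it was 0.221, as for immune markers, where only CSF1R of 14 listed genes was tested, and for apoptosis regulators it was 0.466. It was 0.538 for DNA replication, for YAP/TEAD targets and for endothelial markers, 0.555 for MHC class I, 0.557 for microRNA machinery, 0.858 for neuronal markers, 0.865 for mTORC1 components and for glial markers, and 0.95 for epithelial genes. The lists of mTORC1 components and neuronal markers had means of -0.01 while camera gave the direction as up. Without control replicate 3, lists that passed by camera were extracellular matrix (0.00147), mesenchymal (0.00575), interferon (0.00751) and Wnt (0.0314), all higher in siRBM47, and ribosomal proteins (5.97e-05), DNA replication (0.00132), mitochondrially encoded (0.00575) and oxidative phosphorylation genes (0.0271), all lower. With an estimated correlation none of these 8 lists passed without control replicate 3 (adjusted p = 0.399 to 0.623 with an estimated correlation). COL1A1, a fibrillar collagen, was at 578, 571 and 1780 CPM in control replicates 1, 2 and 3 and at 2050 ± 628 in siRBM47, and the ribosomal protein gene RPL8 at 2500, 2150 and 937 against 994 ± 253.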

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

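The quality weights and the length and GC offset were chosen after seeing the data, and the other settings before. The quality weight was 0.134 for control replicate 3 and 0.334 for siRBM47 replicate 1, against 1.426 to 4.29 for the other libraries. That setting is therefore not independent of leaving out control replicate 3. RLE and upper-quartile factors left the counts at 32 genes and 9 lists. The count of 32 genes (12 higher, 20 lower, 32 at least 2-fold) became 644 (261, 383, 374) with DESeq2, 804 (326, 478, 517) with no low-count filter, 5880 (2895, 2985, 1557) with quality weights and 145 (60, 85, 102) with the length and GC offset; a minimum count of 50 gave 19 higher genes. Leaving out a library gave 0 to 3117 genes, 0 to 1473 higher, 0 to 1644 lower and 0 to 1183 at least 2-fold, with 2 libraries left in a group; the other causes were not tested. Of the 33 lists, 0 passed with an estimated correlation or by fry, and 6 to 14 passed when a library was left out; of the 9 lists, 6 or 7 were kept in each of these fits, and 6 of the 14 without control replicate 3 were among the 9. Of the 9 lists, 6 were kept with quality weights (13 passed) and 6 with the length and GC offset (6 passed); the integrated stress response, lysosome and immediate early lists were lost in both.

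Whether equal replicate numbers pair the libraries was not decided. Same-numbered libraries correlated at -0.04, 0.13 and 0.12 in their deviations from the group means, and differently numbered ones at -0.21 to 0.20. With the replicate number as a block, 39 genes and 9 lists passed (15 genes higher, 24 lower), 26 of the 32 genes were kept, and RBM47 turned to 0.12. With the replicate block the named genes BCL3, CEBPB and HSPA5 no longer passed (edgeR adjusted p = 0.0523, 0.0535 and 0.0717). RBM47 turned to 0.10 with limma-voom and 0.50 with quality weights, and over the fits with a library left out it ran from -0.39 to 0.76, above 0 without control replicate 3 or siRBM47 replicate 3. Its adjusted p lay between 0.152 and 0.984, and it was removed by the minimum count of 50.

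The other values that turned sign were all of genes and lists not past the threshold. ADAR ran from -0.24 to 0.29 with a library left out and was 0.32 with quality weights, HNRNPR was -0.05 with the offset, and KRT18 ran from -1.40 to 0.54 with a library left out. For lists that turned direction the values are adjusted p, with the range over libraries left out. DNA replication ran from 0.00132 (without control replicate 3, direction kept) to 0.923. Epithelial genes ran from 0.308 to 0.997 and gave 0.738 at a minimum count of 50, 0.529 with weights and 0.713 with the offset. Glial markers ran from 0.351 to 0.93 and gave 0.612 with no filter and 0.932 with weights. Immune markers gave 0.982 with no filter. Mitochondrially encoded genes ran from 0.00575 (without control replicate 3, direction kept) to 0.923, and mTORC1 components from 0.391 to 0.95. Neuronal markers gave 0.982 with no filter and 0.979 with weights. RBM47-related proteins ran from 0.882 to 0.997 with a library left out and gave 0.982 with no filter and 0.738 with the offset. YAP/TEAD targets ran from 0.241 to 0.769 and gave 0.570 with weights. The cause was not tested. The 21 genes named by size or p stayed past the threshold in 8 to 12 of 15 alternatives each.

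The planned change of pseudocount was not run because the files hold counts. RBM47 had 24 to 108 counts per library, which sets its counting intervals.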

Other observations

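Of the tests in this part, only that of gene length and GC bias was written before its result was seen; the others were chosen or reworded after. Some genes past the threshold fell outside the rule for naming because of low abundance, and those given here were chosen after their values were seen. EDN1, which encodes the vasoconstrictor endothelin-1, rose from 0.503 ± 0.370 CPM in control to 11.8 ± 0.457 in siRBM47 (SD, n = 3; log2 fold change 4.53, SE 0.48, edgeR adjusted p = 0.00955). SOAT2, which esterifies cholesterol, rose from 1.32 ± 0.566 to 8.32 ± 2.03, and the chemokine receptor ACKR3 from 1.85 ± 0.391 to 6.82 ± 0.762. The transcription factors FOXF1, HES7 and NR4A2 fell, with log2 fold changes of -2.75 (SE 0.34), -2.77 (SE 0.40) and -1.98 (SE 0.30).

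Control replicate 3 lay apart from control replicates 1 and 2, and no biological explanation was tested. Gene length and GC bias is argued against as the whole cause: with each library's trend removed, its root mean square log2 distance from the other two controls went from 0.818 to 0.774, above the 0.527 of the next library. A mix of RNA of both groups and nothing else is argued against by 124 genes in which it lay at least 2-fold above or below all other libraries, where no other library had more than 4. A wrong group label and nothing else is argued against in the same way. Genes at least 2-fold apart were called from control replicates 1 and 2 against 2 siRBM47 libraries, and positions set with these controls at 0 and siRBM47 at 1. The 3 sets so called held 1188, 1364 and 1118 genes, without siRBM47 replicate 1, 2 and 3 in turn. In these sets, 212 to 237 genes of control replicate 3 lay under 0.25, against 16 to 73 for the siRBM47 library left out. Most genes of each set thus lay at 0.25 or above in control replicate 3. RNA from immune, endothelial, epithelial or neuronal cells is argued against as the whole cause. For 470 of 9831 genes with a mean of at least 8 CPM, the share of counts in control replicate 3 was at most 0.5 times that in each of the other two controls, which by dilution needs a share of other RNA of at least 0.5. The median level of the marker lists in it was 0, 0.37, 0.75 and 0.8 CPM in this order, so cells making up that share would hold their own markers at medians of at most 1.6 CPM. An earlier test on these lists did not decide: the highest share of markers highest in control replicate 3 was 0.4, for epithelial genes, with an exact upper bound of 0.74. KRT8 was at 36.84 CPM against 22 and 17.26 in the other two controls, and KRT18 at 0.266 against 3.05 and 0.691, with 16.3% of the exon length of KRT18 overlapped by KRT8 on the opposite strand. A wrong label together with another difference stays open. Over the 3117 genes called without control replicate 3, its median position was 0.88, within the 0.86 to 1.13 of the siRBM47 libraries. The siRBM47 libraries helped to call these genes and set position 1, so their own range was not held out. In the 3 sets above, the siRBM47 library left out had medians of 0.92, 0.79 and 0.95, and control replicate 3 lower ones of 0.76, 0.76 and 0.77. On the side of the control label, NR1D1 was at 68.1 CPM in it, against 70.1 and 72.8 in the other two controls and 17.3 to 18.7 in siRBM47, and MT1E at 101 against 634 to 767 in siRBM47, genes picked with its control label in use. The NF-kB list lay at 0.48 in it, in median centred log2 CPM, against 0.61 and 0.60 in the other two controls and -1.04 to -0.11 in siRBM47, and the unfolded protein response list at 0.53 against 0.15 and 0.18 and -0.43 to -0.29; these lists too were called with its control label in use. Other called lists include cytoskeleton, which goes with a wrong label. It lay at 0.17 in control replicate 3, against -0.25 and -0.24 in the other two controls and 0.07 to 0.27 in siRBM47. Cholesterol synthesis lay outside both groups, at 0.58 in control replicate 3 against -0.56 and -0.47 in the other two controls and 0.16 in each siRBM47 library. A sample from outside the study and RNA of other cell types were not tested.

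A lower level of RBM47 was not detected in the libraries labelled siRBM47, where the log2 fold change was -0.11. Too few counts are argued against as the reason that a halving was not seen, since the exact 95% interval of the pooled ratio, siRBM47 over control, was 0.71 to 1.12 from 152 and 162 counts, for counting error only. The spread between all libraries leaves a halving open, since the edgeR interval over them reaches down to a ratio of 0.43. That limit rests on control replicate 3. Without control replicate 3 the edgeR interval reaches down to a ratio of 0.98, and the pooled ratio was 1.69 (1.23 to 2.35). A depletion acting on the protein alone, the timing of the harvest and a wrong label were not tested on this gene.

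The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split gave 32 genes and the highest of the others 0 by edgeR, so 1 of 10 splits gave as many; at an unadjusted p under 0.05 the real split gave 2347 genes and control replicates 1 and 2 with siRBM47 replicate 2 against the rest gave 2724.

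A hypothesis drawn from NR1D1, PER1 and DBP was that the circadian clock may be shifted as a whole. Other clock outputs, 8 tested of 9 listed, had a median log2 fold change of -0.34 with 7 of 8 negative, and fry (limma) gave an adjusted p = 0.171 over the 3 lists tested in this way (0.114 before adjustment), so the hypothesis was not decided. The list included CIART, which had been seen earlier as low in control replicate 3; with CIART removed, after the first result was known, fry (limma) gave an adjusted p = 0.0705 (0.0235 before adjustment, median -0.35), and this second value is not counted because the removal followed the result. Without control replicate 3 both versions gave an adjusted p = 0.114 (0.0625 and 0.0757 before adjustment; fry, limma). CRY2 was nearest to the threshold, at -1.03 (SE 0.25, edgeR adjusted p = 0.111), and without control replicate 3 it was called lower at -1.12 (edgeR adjusted p = 0.00406).

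A hypothesis drawn from MT1E and MT1F was that a metal response may be shared by the metallothionein family. The other members and the zinc exporter SLC30A1, 5 tested of 9 listed, had a median log2 fold change of 0.30, 3 positive and 2 negative, and fry (limma) gave an adjusted p = 0.555, so the hypothesis was not decided. The median turned to -0.07 without control replicate 3 (fry, limma, adjusted p = 0.51). MT2A was at 4570, 3590 and 1320 CPM in the control libraries and at 4320, 3670 and 3650 in siRBM47, and SLC30A1 at 4.06, 5.18 and 14.1 against 15.4, 13.9 and 14.2. MT1M and MT1L went the other way, with log2 fold changes of -0.40 and -0.42 (edgeR adjusted p = 0.817 and 0.483). Without control replicate 3 they were called lower, at -0.94 and -0.70 (edgeR adjusted p = 0.00762 and 0.00404), and SLC30A1 higher at 1.65 (edgeR adjusted p = 0.000353). The reservation on counts of MT1E and MT1F, where reads fit more than 1 copy, holds for MT1M, MT1L and the other metallothionein genes too.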
